A study of Homo sapiens
Mus musculus and Homo sapiens and Mus musculus with 20 samples.

How the data were processed

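RNA of the human breast cancer cell line MDA-MB-231 and RNA of mouse astrocytes were mixed in 7 proportions. Each of the 10 samples was hybridised to an Illumina Human-6 version 2 BeadChip and to an Illumina mouse BeadChip, giving 20 arrays. Per the labels, 500 ng of total RNA was converted to biotin-labelled complementary RNA by amplification. The bead images were summarised in BeadStudio per the submitters' processing notes, and its version is not given in the sources used here. The deposited raw tables give average bead intensity per probe, per the file headers, with no background subtraction visible in the values. The deposited processed tables are log2 of that intensity, equal to the raw tables within 0.0001 and without normalization between arrays. The third pair of deposited tables, the series matrices, holds the same log2 values as the authors gave them. No file used here gives a detection p-value.

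The raw human table has 48687 entries, but 1974 probe keys occur 2 times in it. The first entry of each key is the one in the processed table, and it was kept, leaving 46713 probes. Series matrix probes were matched to the raw table by their values: 46693 matched exactly 1 entry each, and 20 keys had no match. All 46628 mouse probes were matched. Gene symbols of the human probes came from the platform annotation, which can lag behind current gene models: 22181 probes had 1 symbol (18703 genes), 35 had several and 24497 had none. Mouse probes had no symbols in the annotation used here. Their identifiers name 13 mitochondrial transcripts, 352 immune receptor gene segments, 37 reporter, vector or bacterial control sequences and 4 ribosomal RNAs, and 24 spike and primer controls were left out of the tests. The other 46198 mouse probes stay unnamed.

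Signals were background-corrected per array with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50, and put on the log2 scale. Arrays were not normalized to each other, because total signal of 1 species is meant to change with its share. A probe counted as above background where its deposited signal exceeded the mode of the array's signals by 3 SD, the SD being taken from the values below the mode. Probes above background on at least 1 array of a type were tested: 17392 on the human arrays and 24278 on the mouse arrays. "Own share" is the human share on the human arrays and the mouse share on the mouse arrays. The trend is a linear term for the own share, from 0 to 1, in limma's linear model with empirical Bayes moderation, so its slope is the fitted log2 change between pure RNA of the other species and pure RNA of the own species. Shares with 2 arrays were also compared as 70% against 30%, 70% against 50% and 50% against 30%, in a model with 1 mean per share. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Sample identifiers pair the 2 array types of 1 mixture, not the shares compared, so no pairs entered the models.

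Species-specific probes were above background in pure RNA of the own species, not above background in pure RNA of the other, and at least 4-fold brighter in the own. The measured share of a mixture is the median over these probes of the deposited signal minus that of the other pure RNA, divided by the difference between the pure RNAs. Its relation to the labelled share was tested over the 8 mixed arrays of a type by Pearson and Spearman correlation with exact permutation p-values. Confidence intervals of 95% for ratios came from 1000 bootstrap resamples over probes. These calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

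Gene lists, comparisons, the rule for named genes and most alternatives were set before the data were examined. The 18 lists were MDA-MB-231 mesenchymal and basal genes, luminal epithelial genes, markers of astrocytes, of microglia and macrophages, of the oligodendrocyte lineage, of neurons, of fibroblasts with meningeal and mural cells, and of endothelium, cell cycle, glycolysis, interferon response, cytokines with the NF-kB response, extracellular proteases and their inhibitors, cytoskeleton and housekeeping genes, ribosomal proteins, proteasome subunits, respiratory chain subunits and core histones. Core histones were listed under older symbols, matched 0 genes and were not tested. Each gene was represented by its probe with the highest mean, and lists were tested with camera at an inter-gene correlation of 0.01 on the human arrays. Lists were not tested on the mouse arrays, for want of gene symbols. Named genes are the 10 with the largest positive and the 10 with the largest negative slope among those past the threshold, up to 4 members per list with the largest slopes in size, list members called against their list's majority, the 10 brightest in pure RNA of the other species, and GFAP, VIM, CD44, ACTB and GAPDH. On the mouse arrays the probes named by identifier are given instead, and those were chosen after their values were seen.

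Alternatives were no background correction, subtraction of the mode, quantile normalization, scaling to the 75th percentile, the processed and series matrix values, no filter, above background on at least 3 arrays, thresholds of 2 and 5 SD, an intensity trend with robust empirical Bayes, each array left out in turn, mixed arrays only, linear signal, the pure RNAs alone in a group means model, only the 4 arrays compared, and for the shares other probe sets. For the lists they were an estimated correlation, the fry test and the mean of all probes of a gene. Added after seeing the data were the array series as a block, each series alone, a threshold of 7 SD, 75th percentile scaling for the lists, and scaling by probes about equally bright on both pure arrays (at least 1000 on each and within 1.25-fold: 81 human and 95 mouse probes). The array series is inferred from the labels: 4 arrays of each type are numbered 1 and 6 carry s or t.

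In data simulated with the spread of each probe around its share means, with 200 changed probes, the human trend recovered 62% of slopes of 0.5, 84% of slopes of 1 and 100% of slopes of 2, with 11 false calls; the mouse trend recovered 48%, 82% and 100%, with 15. The 70% against 30% comparison recovered 76% of changes of 1 on the human arrays, with 1 false call, and 66% on the mouse arrays, with 5. These simulated slopes were straight lines on the log2 scale, which real mixtures need not follow. The measured share was off by at most 0.128 percentage points in simulated mixtures. Those were exact blends of the pure arrays with added noise and no differences in array brightness. They check the calculation and do not show its accuracy on real arrays. With 10 arrays per type and at most 2 per share, the number of arrays limits the precision.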

Results

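The data are a dilution series of RNA from 2 species. RNA of MDA-MB-231, a human breast cancer cell line of mesenchymal type, was mixed with RNA of mouse astrocytes, the star-shaped support cells of the brain. The human share was 100%, 90%, 70%, 50%, 30%, 10% or 0% and the mouse share made up the rest. The shares of 70%, 50% and 30% have 2 arrays each per array type, named t1 and t2 (70% human), s1 and s2 (50%) and t3 and t4 (30% human). The other 4 shares have 1 array each and no replicates. Because the duplicates may be technical, all p-values speak only for these samples. In the trend the residual spread also holds departures from a straight line on the log2 scale. A probe that did not pass there may therefore still rise with the share. On the human arrays 14652 probes were above background in pure human RNA and 4054 in pure mouse RNA. On the mouse arrays 20669 were above background in pure mouse RNA and 6690 in pure human RNA. Median deposited signals ran from 70.4 (30% human, t3) to 86.9 (pure human RNA) on the human arrays and from 44.9 (30% mouse, t1) to 70.4 (pure mouse RNA) on the mouse arrays.

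**Figure D1:**
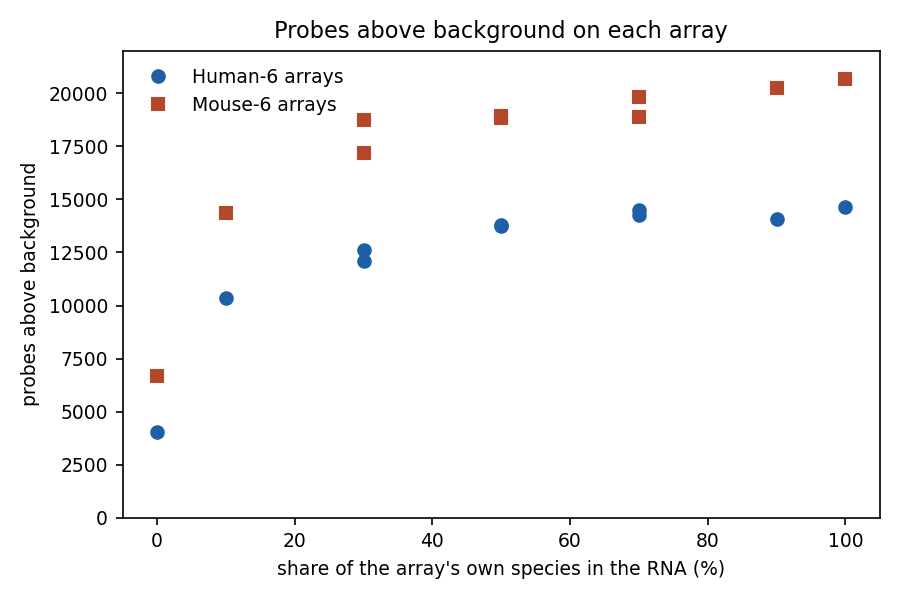
Number of probes above background (y axis) against the labelled share of the array's own species in percent (x axis), 1 point per array, with human arrays and mouse arrays drawn apart. Counts climbed from 4054 to 14652 on the human arrays and from 6690 to 20669 on the mouse arrays.

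The first question is which transcripts of the cancer cell follow the human share. Genes at the top of the human array trend were bright in MDA-MB-231 RNA and at background in astrocyte RNA. These are signals of human probes, so a low signal or a fold in mouse RNA does not measure expression in astrocytes. SLC25A51, a mitochondrial carrier of NAD, had a signal of 28504 in pure human RNA and 67.1 in pure mouse RNA, at least 316-fold higher, and a slope of 6.22 ± 1.44 (log2, SE, 10 arrays; adjusted p = 0.00252). CD44, the hyaluronan receptor typical of mesenchymal breast cancer cells, had 21231 against 57.4 (at least 235-fold higher; slope 5.72 ± 1.67, adjusted p = 0.00948). GAPDH, a glycolytic enzyme, had 21979 against 74.7 (at least 243-fold higher; slope 5.70 ± 1.52, adjusted p = 0.00571). VIM, the intermediate filament vimentin that both cell types make, had 33561 in human and 2691 in mouse RNA, 12.5-fold higher in human RNA, with a slope of 2.82 ± 0.58 (adjusted p = 0.00120). "At least" marks a bound: the corrected signal of the bright RNA is set against the lowest signal above background in the dim RNA, or the probe's own if higher. The other named genes with the steepest slopes were USP49 (6.08), SNRPG (5.93), ALPP (5.91), MCM8 (5.89), COX7C (5.88), SDHAP1 (5.88), RPS6 (5.86), HSD17B7 (5.85) and RPL14 (5.83). Other, dimmer probes of several of these genes had small slopes, 0.93 for HSD17B7, -0.0083 for MCM8 and 0.24 to 1.46 for SDHAP1, and 1.96 for CD44. At 30% human RNA USP49 stood at 8.86% and 9.22% of its pure signal, under the 10.4% at a label of 10%, and SLC25A51 at 15.6% and 13.9% against 14.4%. The 10% mixture is on an array numbered 1 and the 30% mixtures are in the other series.

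In limma's trend over the 10 human arrays 13772 of 17392 probes rose with the human share, 330 fell and 3290 did neither. The median slope was 1.39 over all probes and 3.41 over the 6220 human-specific ones, whose rise follows from their selection on the pure arrays, which are part of the trend. With the array series as a block 14556 rose and 413 fell, within the 4 arrays numbered 1 13148 rose and 412 fell, and within the 6 arrays labelled s or t 10226 rose and 117 fell. Scaling arrays to each other moved the median slope by -0.97 (quantile normalization, 2866 rising and 1589 falling) and by -0.65 (75th percentile, 10220 rising and 4274 falling), so called directions depend on the scaling. The 75th percentile of the deposited log2 signal was itself 6.41 in pure mouse and 7.04 in pure human RNA. Scaling to that percentile shifts every slope by the same -0.65, so a flat probe at background comes out as falling. Falls under it are relative to the percentile and do not by themselves show a falling signal. Scaling by probes about equally bright in both pure RNAs, an alternative chosen after seeing the data, moved it by -0.031 and left 13380 rising and 432 falling. Under quantile normalization the steepest named genes, CD44 and GAPDH did not pass (adjusted p from 0.0582 for USP49 to 0.0883 for CD44). Genes with several probes did not always move together: across 838 such genes (not independent replicates) the probe slopes had a Spearman rho of 0.396, and 33 genes had probes called in opposite directions.

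**Figure D2:**
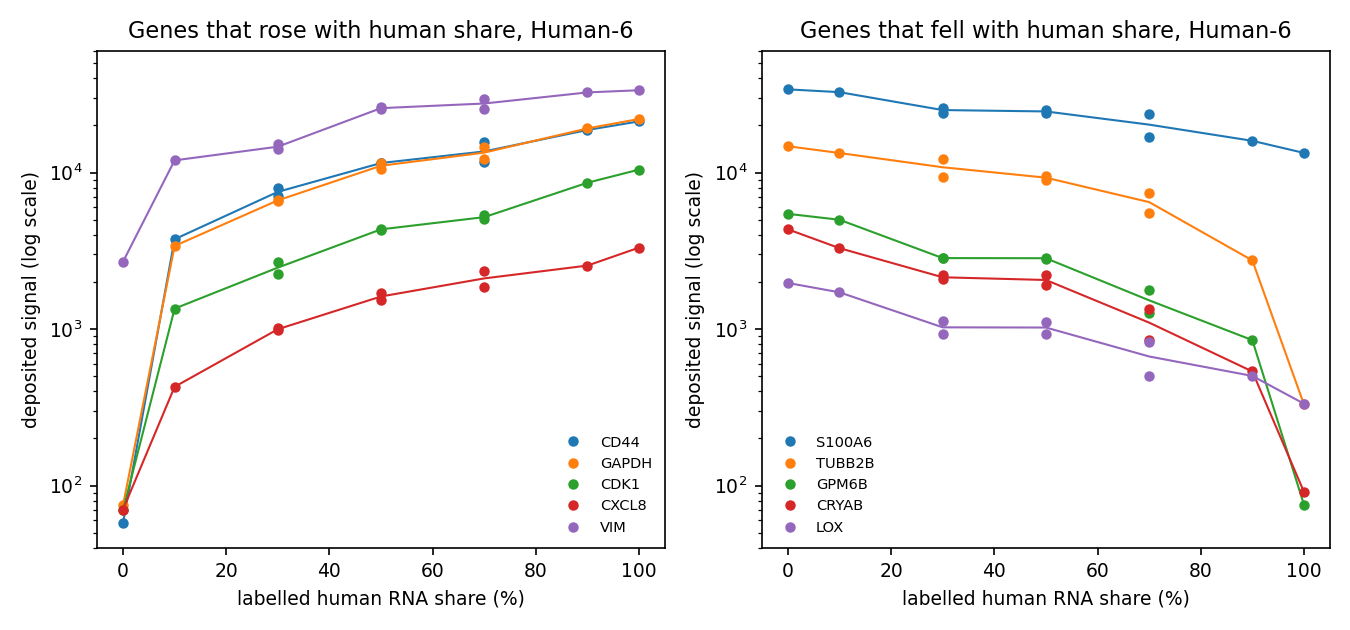
Deposited signal (intensity, log axis) of named genes on the human arrays against the labelled human share in percent, with points for single arrays and lines joining the means; the left panel holds CD44, GAPDH, CDK1, CXCL8 and VIM, the right panel S100A6, TUBB2B, GPM6B, CRYAB and LOX. CD44 went from 57.4 in pure mouse RNA to 21231 in pure human RNA, while TUBB2B went from 14726 to 330.1.

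On unscaled signal most genes rose, 10055 of all 11563 tested, and the list counts are to be read beside that. Of 25 mesenchymal and basal genes 21 rose, 3 fell and 1 did neither, with a median slope of 3.32. Adjusted over the list alone the counts were 21 and 3. Among those that rose were ITGB1 (5.66), an integrin chain, TGFBI (5.65), a matrix protein induced by TGF-beta, and the receptor tyrosine kinase AXL (5.28). Those that fell were brighter in astrocyte RNA: LOX, which crosslinks collagen (slope -2.31; 333.5 in human and 1970 in mouse RNA), ZEB1, a repressor of epithelial genes (-1.67; 139.2 and 446.3), and the calcium-binding protein S100A6 (-1.24; 13344 and 33997). All 9 tested luminal epithelial genes rose (9 adjusted over the list alone, median slope 2.07), led by the keratin KRT8 (3.85), XBP1 (3.35), the keratin KRT18 (2.29) and the adhesion molecule EPCAM (2.19). The array has 20 luminal genes, and those not tested were at background on every array. Of 17 cytokine and NF-kB genes 15 rose (15 adjusted over the list alone), 0 fell and 2 did neither (median 2.31), with the chemokines CXCL1 (4.56) and CXCL8 (4.42) and the interleukins IL1A (4.07) and IL11 (3.60) as examples. Of 18 interferon-response genes 17 rose and 1 fell (the same counts adjusted over the list alone; median 3.17): IFITM3 (4.99), IFITM2 (4.76), IFIT2 (4.69) and ISG15 (4.53) rose, and IFITM1 fell (-1.55; 559.1 in human and 1766 in mouse RNA). Of 17 extracellular proteases and inhibitors 15 rose, 1 fell and 1 did neither (15 and 1 adjusted over the list alone; median 1.88). The urokinase gene PLAU (5.20), TIMP1 (5.01), SERPINE2 (4.64) and CTSL (4.07) rose, and the metalloproteinase inhibitor TIMP2 fell (-2.37; 291.2 in human and 1679 in mouse RNA). The probe key of TIMP2 occurs 2 times in the raw table, so which probe this signal belongs to is uncertain. With arrays scaled by equally bright probes the counts of rising and falling genes were the same for these lists, except for 4 falling mesenchymal genes. Under quantile normalization 2 mesenchymal genes rose and 5 fell, 4 luminal rose and 0 fell, 4 cytokine genes rose and 1 fell, 2 interferon genes rose and 1 fell, and 1 protease gene rose and 2 fell. Under 75th percentile scaling the counts were 18 and 5, 8 and 0, 12 and 2, 14 and 3, and 14 and 2.

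The growth and metabolism lists, too, are to be read beside the 10055 of 11563 genes tested that rose on unscaled signal. All 26 cell cycle genes rose (26 adjusted over the list alone; median 3.75), including the mitotic kinases CDK1 (5.31) and AURKA (5.26), thymidylate synthase TYMS (5.26) and RRM1 (5.23). Of 14 glycolysis genes 13 rose (13 adjusted over the list alone; median 4.40), with ENO1 (5.83), LDHA (5.59) and PGK1 (4.92) beside GAPDH. All 74 respiratory chain subunits rose (74 adjusted over the list alone; median 4.49), such as COX7C, NDUFS5 (5.77), ATP5PD (5.71) and NDUFS6 (5.68). Of 67 ribosomal protein genes 63 rose, 0 fell and 4 did neither (64 rose adjusted over the list alone; median 3.99), with RPL19 (5.76) and RPL10A (5.75) beside RPS6 and RPL14. Of 31 proteasome subunits 27 rose and 4 did neither (27 adjusted over the list alone; median 3.50), led by PSMC1 (5.79), PSMB7 (5.40), PSMC3 (5.17) and PSMC2 (4.96). Of 21 cytoskeleton and housekeeping genes 16 rose and 5 did neither (16 adjusted over the list alone; median 1.88), with TUBB (5.66), UBB (5.43), TUBA1B (5.34) and EEF2 (5.32) steepest. TUBA1B (adjusted p = 0.0461) did not pass under 75th percentile scaling (0.0741), with arrays scaled by equally bright probes (0.0633) or under quantile normalization (0.0908). The actin gene ACTB rose by a slope of 1.13, having 9395 in human and 4648 in mouse RNA, but its slope turned to -1.28 under quantile normalization. Under that normalization 5 cell cycle genes rose and 2 fell, 1 glycolysis gene rose and 1 fell, 3 respiratory chain subunits rose and 5 fell, 6 ribosomal protein genes rose and 7 fell, 1 proteasome subunit rose and 8 fell, and 1 cytoskeleton or housekeeping gene rose and 6 fell. Under 75th percentile scaling these were 26 and 0, 13 and 1, 73 and 0, 54 and 3, 25 and 4, and 12 and 2. With arrays scaled by equally bright probes they were 26 and 0, 13 and 1, 73 and 0, 59 and 0, 27 and 0, and 16 and 0.

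Markers of brain cells were read by human probes with signal from either RNA, so values in mouse RNA do not measure expression in astrocytes. Only markers above background on at least 1 array were tested, for example 7 of 20 microglia and macrophage markers. Their counts, too, stand beside the rise of most genes on unscaled signal. GFAP, the classic astrocyte filament protein, stayed at background on the human arrays in both pure RNAs (100.1 and 96.1). Its slope in the trend was 0.13 (adjusted p = 0.349), or -0.52 under 75th percentile scaling (adjusted p = 0.00110). That scaling shifts every slope on the human arrays by -0.65, so the second value shows no fall of GFAP itself. Of 12 astrocyte markers tested 7 rose, 1 fell and 4 did neither (7 and 1 adjusted over the list alone; median 0.68, or 0.25 under quantile normalization and 0.031 under 75th percentile scaling): CST3 (5.07), a secreted protease inhibitor, SOX9 (3.54), the gap junction gene GJA1 (3.51) and ALDOC (2.91) rose, and the lipid carrier APOE fell (-1.94; 98.0 in human and 467.4 in mouse RNA). Of 7 microglia and macrophage markers 6 rose and 1 did neither (6 adjusted over the list alone; median 0.59, or -0.060 under 75th percentile scaling), among them CD68 (5.15), LAPTM5 (3.59), CSF1R (2.41) and PTPRC (0.59, or -0.060 under that scaling). Of 7 oligodendrocyte lineage markers 6 rose and 1 did neither (6 adjusted over the list alone; median 0.93): CLDN11 (3.73), UGT8 (1.96), MBP (2.46) and CSPG4 (0.93) rose, but MBP turned to -1.0 and CSPG4 to -1.36 under quantile normalization. Of 9 neuron markers 6 rose, 2 fell and 1 did neither (6 and 2 adjusted over the list alone; median 0.36, or -0.19 under quantile normalization and -0.29 under 75th percentile scaling). The tubulin TUBB3 (4.27), GAD1 (2.58) and SNAP25 (1.67) rose, while STMN2 (-3.02; 92.9 in human and 1014 in mouse RNA) and ELAVL3 (-0.82) fell. Of 12 fibroblast, meningeal and mural markers 8 rose (7 adjusted over the list alone), 0 fell and 4 did neither, with a median of 0.34 that turned to -0.028 under quantile normalization and -0.31 under 75th percentile scaling. TAGLN (4.50), COL5A1 (3.77), COL1A1 (2.66) and FBLN1 (1.90) rose. Of 10 endothelial markers 7 rose and 3 did neither (7 adjusted over the list alone; median 0.64, or -0.17 under quantile normalization and -0.0078 under 75th percentile scaling), with ENG (3.44), ESAM (2.44), ROBO4 (1.88) and EGFL7 (1.15). Scaling by equally bright probes left the rising and falling counts of all 6 brain-cell lists the same. Under 75th percentile scaling 5 astrocyte markers rose and 5 fell, 3 microglia markers rose and 1 fell, 4 oligodendrocyte markers rose and 1 fell, 3 neuron markers rose and 5 fell, 5 fibroblast markers rose and 6 fell, and 4 endothelial markers rose and 4 fell. Under quantile normalization the counts were 0 and 1, 0 and 0, 1 and 0, 1 and 3, 2 and 0, and 2 and 0.

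Camera set the moderated t-statistics of each list, slopes divided by their SE, against those of all 11563 genes tested, whose median slope was 2.07. It called 2 of 17 lists, both downward: the neuron markers (adjusted p = 0.00223) and the mesenchymal and basal genes (adjusted p = 0.0237). Neither call held with an estimated correlation, where the adjusted p was 0.675 for the neuron markers and 0.964 for the mesenchymal genes. The neuron list had a median slope of 0.36 and a mean of 0.67, below the median of all genes, so its direction is relative to them although its slopes were mostly positive. For the mesenchymal list the call and the slopes differ in sign. Its median slope of 3.32 and its mean of 2.82 lie above the median slope of all genes. Its steepest genes had wide SEs, as in CD44 (5.72 ± 1.67), ITGB1 (5.66 ± 1.62) and AXL (5.28 ± 1.24), which makes their t-statistics small. UGT8, an oligodendrocyte marker, had a slope of 1.96 ± 0.15. The downward call thus does not show that the mesenchymal genes rose less than others. Camera called none of the growth and metabolism lists.

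The genes that fell with the human share show which human probes picked up signal from astrocyte RNA. Probe sequences were not used here, so the mouse transcript that each probe bound is not known. GPM6B, a membrane proteolipid of glia and neurons, had 75.5 in human and 5446 in mouse RNA, at least 54.0-fold higher in mouse RNA, and a slope of -4.61 ± 0.96 (adjusted p = 0.00134); another GPM6B probe had a slope of -0.25. The small heat shock protein CRYAB had 91.1 and 4338 (at least 43.0-fold higher in mouse RNA; slope -4.35 ± 0.76, adjusted p = 0.000409). The tubulin TUBB2B had 330.1 and 14726 (45.1-fold higher in mouse RNA; slope -4.04 ± 0.94, adjusted p = 0.00265). The other genes with the steepest falls were GSTA5 (-4.62), DPYSL3 (-4.27), SIGLEC12 (-4.09), PCDH19 (-3.98), the histone H2AC4 (-3.91), CLIP3 (-3.89) and ACTC1 (-3.83). The 10 human genes brightest in pure mouse RNA were headed by S100A6 (33997) and RPS27 (32246). Of these 10, S100A6 fell, while RPS27 (slope 0.31), SLC25A5 (0.67) and PTMA (0.79) rose, but under quantile normalization the slopes of these last genes were -0.14, -0.15 and -0.062, and that of RPS27 was -0.34 under 75th percentile scaling. In the trend under 75th percentile scaling SLC25A5 (adjusted p = 0.865) and PTMA (0.536) did not pass. RPS27 did not pass with arrays scaled by equally bright probes (adjusted p = 0.339). Another RPS27 probe had a slope of 4.29. RPL30 (-0.19), LGALS1 (-0.34), H2AZ1 (0.36), TPT1 (0.092), SUMO2 (0.095) and RPL13AP3 (0.15) did not pass the test. Their signal was not level: SUMO2 had 25553 in human and 24552 in mouse RNA but 14058 to 18058 on the arrays labelled s or t, and H2AZ1 ran from 17296 to 31796. Under quantile normalization all of these fell (adjusted p from 8.25e-05 for LGALS1 to 0.0474 for H2AZ1). RPL30, LGALS1, TPT1 and RPL13AP3 also fell under 75th percentile scaling (the highest adjusted p, for RPL13AP3, being 0.0125) and LGALS1 with arrays scaled by equally bright probes (adjusted p = 0.000573). H2AZ1 rose with the series as a block (adjusted p = 0.0422).

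The mirror question is which probes of the mouse arrays follow the astrocyte share. Among the named probes, those for mitochondrial transcripts were bright in astrocyte RNA: 12 of 13 were above background in pure mouse RNA and 1 in pure human RNA, with median signals of 30916 and 56.9. Mitochondrial ND4 (slope 5.73, adjusted p = 0.0238) and CytB (5.71, adjusted p = 0.0253), parts of the respiratory chain, rose with the mouse share, as did ND4L (5.66), ND2 (5.63), ND1 (5.40), COXIII (5.31), ATP8 (5.10), ND5 (4.82) and COXI (4.01). ND3 was called as rising too (3.94), but it did not follow the share across the array series, with 348.9 at 10% and 59.6 and 49.5 at 30%. COXII (5.06, adjusted p = 0.0505) and ATP6 (4.84, adjusted p = 0.0751) did not pass. Both were far brighter in pure mouse than in pure human RNA, at least 451-fold (COXII) and 415-fold (ATP6). Not passing is thus no sign of an absent rise in them. ND6 stayed at background (65.6 in pure mouse RNA). None of the mitochondrial probes passed under quantile normalization. Under 75th percentile scaling ND1 (adjusted p = 0.0772), COXIII (0.0769), ATP8 (0.0757) and ND3 (0.0530) also lost the call, and with arrays scaled by equally bright probes ND1 (0.0613), COXIII (0.0606) and ATP8 (0.0581) did. In the other direction the probes for retroviral long terminal repeats fell with the mouse share. The 3' repeat of Moloney murine leukemia virus had 22685 in pure human and 56.4 in pure mouse RNA (slope -5.48 ± 1.55, adjusted p = 0.00901), and the 5' repeat of Moloney murine sarcoma virus had 20205 and 53.6 (-5.56 ± 1.62, adjusted p = 0.0106). The neomycin resistance probe NeoR had 8176 and 65.8 (-4.94 ± 1.12, adjusted p = 0.00249), and the green fluorescent protein probe eGFP 3370 and 58.5 (-4.40 ± 0.81, adjusted p = 0.000654). The probe for SV40 large T antigen, a viral oncoprotein, had 51.9 in human and 301.1 in mouse RNA and rose (2.21 ± 0.23, adjusted p = 1.87e-05; 0.0800 under quantile normalization). The probe specific for small t antigen stayed at background in both (51.8 and 62.8).

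**Figure D3:**
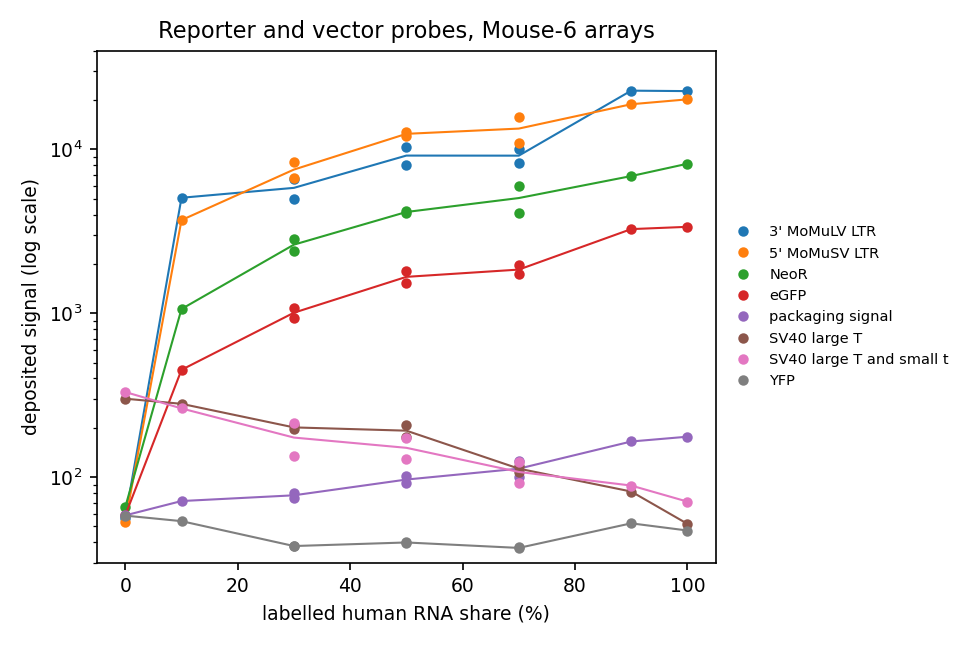
Deposited signal (intensity, log axis) of reporter and vector probes on the mouse arrays against the labelled human share in percent, 1 point per array. Both retroviral repeats, NeoR and eGFP sit between 53.6 and 65.8 in pure mouse RNA and at 22685, 20205, 8176 and 3370 in pure human RNA, while the SV40 large T probe goes the other way, from 301.1 to 51.9.

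In limma's trend over the 10 mouse arrays 17058 of 24278 probes rose with the mouse share, 402 fell and 6818 did neither. The median slope was 0.96 over all probes and 3.13 over the 7496 mouse-specific ones, which were selected on the pure arrays too. The steepest unnamed probes were GI_38077775-S (slope 6.19) and GI_38076122-S (6.08), which stood at 22506 and 14076 in mouse and 47.7 and 47.4 in human RNA. With the array series as a block 18100 rose and 714 fell, within the 4 arrays numbered 1 16331 rose and 459 fell, and within the 6 arrays labelled s or t 11878 rose and 147 fell. Quantile normalization moved the median slope by -0.72 (2063 rising, 1415 falling) and 75th percentile scaling by -1.03 (9835 rising, 10601 falling), while scaling by equally bright probes moved it by -0.0076 (17073 rising, 532 falling). The 75th percentile shift is again the same for every probe. Mitochondrial ND6, at background on these arrays, went from a slope of -0.069 to -1.10 under it.

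The replicated shares ask how closely signal follows the amount of RNA. From 30% to 70% human RNA, CD44 went from 7526 ± 651 to 13640 ± 2787 (SD, n = 2; log2 difference 0.85 ± 0.15, adjusted p = 0.000801) and GAPDH from 6639 ± 24.5 to 13409 ± 1774 (1.01 ± 0.12, adjusted p = 0.000181). RPL14 rose by 1.43 ± 0.14 and VIM by 0.91 ± 0.11, from 14628 ± 802 to 27608 ± 2826. GPM6B, read from mouse RNA, fell from 2840 ± 22.7 to 1526 ± 362 (-0.91 ± 0.15, adjusted p = 0.000661). Mouse mitochondrial ND5 rose from 1509 ± 124 to 3256 ± 94.5 between 30% and 70% mouse RNA (1.10 ± 0.15, adjusted p = 0.00917). The other mitochondrial probes above background in mouse RNA ran from -0.055 (ATP6, adjusted p = 0.680) over 0.30 (COXII), 0.32 (ATP8 and COXIII), 0.33 (ND1), 0.62 (CytB), 0.69 (ND4), 0.77 (ND3) and 0.88 (ND2 and COXI) to 1.44 (ND4L). ND3 stood at 54.5 ± 7.18 at 30%, beside thresholds of 51.1 and 52.4 on those arrays, so its difference is read near background. Probes with small differences were bright at 30% already, ATP6 at 27269 ± 2043 and ND1 at 28585 ± 2369, where the highest signals of these 4 arrays were 33363 to 36090. Saturation is not excluded for them, so their differences do not measure proportion. Strict proportion would give 1.22. The median over the human-specific probes was 1.01 and over the mouse-specific ones 0.91, with 10950 probes higher and 156 lower at 70% on the human arrays and 12005 and 143 on the mouse arrays. On the mouse arrays this call ended, with 0 probes left, when array t4 of the 70% share was left out, and without t1 of the 30% share 7424 probes were left. Scaling turned the medians to 0.12 (human) and 0.11 (mouse) under quantile normalization.

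The narrower steps came out unequal. The proportional values given for them, too, hold for signal without the offset, which makes log2 differences smaller. Between 30% and 50% the human-specific probes rose by a median of 0.80, where proportion would give 0.74, with 9902 probes higher and 5 lower, and the mouse-specific probes rose by 0.63, with 5768 higher and 9 lower. The mouse count fell to 0 without array t1 of the 30% share, without s1 or without s2, and reached 9241 without t2. Between 50% and 70% the medians were 0.22 (human) and 0.25 (mouse), where proportion would give 0.49, and limma called 0 probes on either array type. At an unadjusted p under 0.05, 2334 probes were higher and 330 lower on the human arrays and 1479 and 151 on the mouse arrays. The human 70% duplicates differed: human-specific probes were brighter in t1 than in t2 by a median of 0.34 (log2), and without t2 5601 probes were called, against 278 without t1. With arrays scaled by probes about equally bright in both pure RNAs 7836 probes were called on the human arrays and 3287 on the mouse arrays.

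Shares measured from species-specific probes followed the labels in order and mostly fell short of them in size. On the human arrays the measured share was 10.7% at a label of 10%, 23.4% ± 0.010 (SD, n = 2) at 30%, 47.9% ± 1.35 at 50%, 57.1% ± 11.4 at 70% and 83.6% at 90%. On the mouse arrays it was 12%, 22.1% ± 6.29, 43.0% ± 1.73, 53.3% ± 9.52 and 86.3%. The largest gap to a label was 21.0 percentage points on the human arrays (t2, 49.0% against 70%) and 23.4 on the mouse arrays (t3, 46.6% against 70%), both above the pooled SD between duplicates of 6.62 and 6.66. Human and mouse measured shares of a mixture summed to 95.6% and 97.0% on the arrays numbered 1 and to between 70.0% (t3) and 93.1% (s1) on those labelled s or t.

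**Figure D4:**
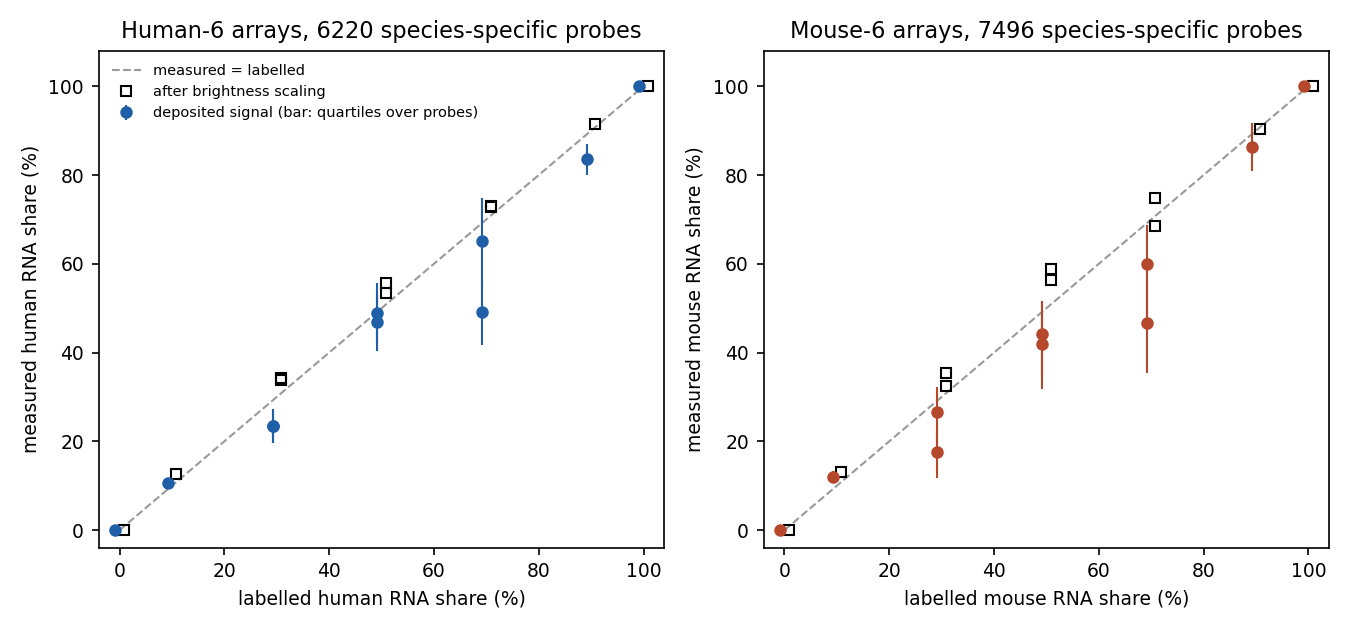
Measured share in percent (y axis) against the labelled share of the array's own species in percent (x axis), 1 point per array, for human and mouse arrays, with the line of equal values. Most mixed arrays lie under the line, the farthest at 49.0% (human array, t2) and 46.6% (mouse array, t3) for a label of 70%.

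Over the 8 mixed arrays, Pearson r between label and measured share was 0.969 and Spearman rho 0.982 on the human arrays, and 0.958 and 0.982 on the mouse arrays. Each exact permutation p was 0.000397, the smallest that these 8 arrays allow, and the adjusted p over the 4 relations tested was the same. Without the 2 arrays farthest from the median label, r was 0.919 (human) and 0.922 (mouse). Those 6 arrays are also the ones labelled s or t, so these are the values within that series; the other series has 2 mixed arrays, too few for a correlation. Array brightness differed beside this: probes about equally bright in both pure RNAs stood at 0.635 to 0.947 of their level in the pure RNAs on the 12 arrays labelled s or t, and at 0.884 to 0.958 on the 4 mixed arrays numbered 1. Scaled to those probes, the measured shares were 12.5%, 34.0% ± 0.270, 54.5% ± 1.49, 72.9% ± 0.134 and 91.4% on the human arrays and 13.0%, 33.9% ± 2.10, 57.6% ± 1.72, 71.7% ± 4.55 and 90.3% on the mouse arrays, with r of 0.999 and 0.992. Under quantile normalization the human shares ran from 71.2% at a label of 10% to 99% at 90%.

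**Figure D5:**
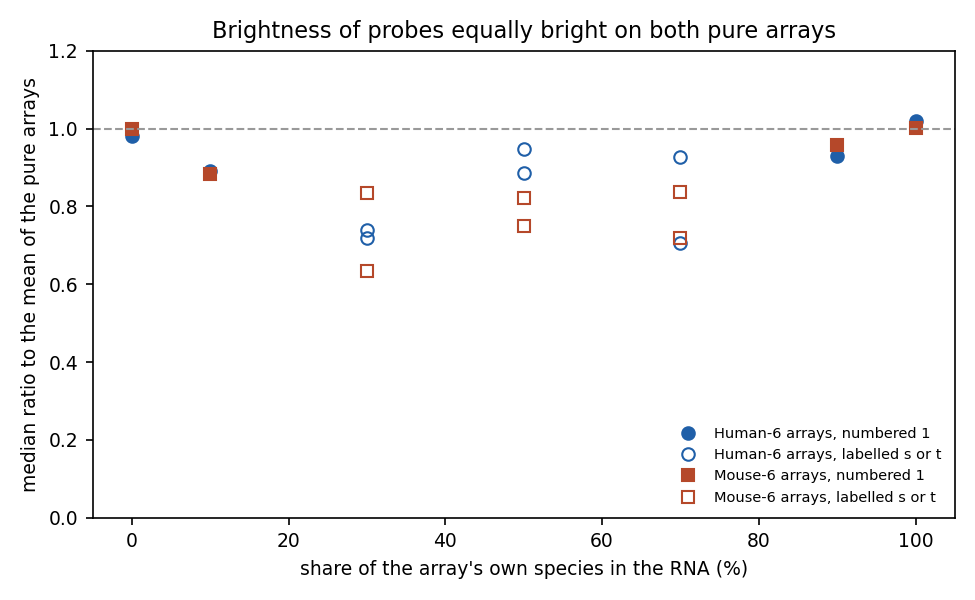
Median ratio to the pure arrays of probes about equally bright in both pure RNAs (y axis) against the labelled share of the array's own species in percent (x axis), filled symbols for arrays numbered 1 and open symbols for those labelled s or t. The 12 open symbols lie between 0.635 and 0.947.

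The last comparison asks how much signal 1 species leaves on the arrays of the other. On the human arrays 4054 of 46713 probes (8.68%) were above background in pure mouse RNA, against 14652 (31.4%) in pure human RNA; 3197 were above in both, and 440 against 4193 exceeded a signal of 1000. On the mouse arrays, controls left out, 6688 of 46604 probes (14.4%) were above background in pure human RNA, against 20666 (44.3%) in pure mouse RNA, with 5742 above in both. The lists were set against random lists on the human arrays and were not tested against each other. Of 21 cytoskeleton and housekeeping genes 12 were above background in mouse RNA, and the list's median signal of 223.4 lay at percentile 99.7 of random lists of like expression. Of 34 proteasome subunits 16 were above background (percentile 95.6) and of 69 ribosomal protein genes 27 (percentile 78.9). Of 28 astrocyte markers 3 (10.7%) were above background (percentile 94.8), while the extracellular proteases and inhibitors lay at percentile 5.21. The median signals of the proteasome (88.1), ribosomal (84.7), astrocyte (81.6) and protease (74.5) lists were under that array's threshold of 98.3. Their percentiles thus rank signal at background and do not show that a list was picked up. No luminal epithelial and no microglia marker was above background in mouse RNA, and of all 18703 named genes 2376 (12.7%) were. The count depends on the threshold: at 5 SD 2266 human-array and 4419 mouse-array probes were above background.

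Most species-specific probes stayed above background in small amounts of their RNA. They were chosen as at least 4-fold brighter in pure RNA of their species, which favours this result. The percentages do not hold for all probes above background in pure RNA, which were 14652 on the human arrays. Of the 6220 human-specific probes 5850 (94.1%) were above background at 10% human RNA and 6189 and 6190 (99.5%) at 30%. Of the 7496 mouse-specific probes 6954 (92.8%) were above background at 10% mouse RNA. The cell cycle gene CDK1 had 10443 in pure human RNA and 2469 ± 313 (SD, n = 2) at 30%, and the chemokine CXCL8 had 3314 and 997.4 ± 20.4.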

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

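The tests for unspecific binding, for transcripts carried by the human or by the mouse cells and for saturation were chosen only after the results they measure were seen, and so was the scaling by probes about equally bright on both pure arrays; the other tests were chosen before.

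Of 37 probes for reporter and vector sequences on the mouse arrays, which no comparison of the labels concerns, 7 were above background in pure human and 3 in pure mouse RNA, a zebrafish Alk7 probe in both (106.3 and 107.2). In pure human RNA the probe for the 3' long terminal repeat of Moloney murine leukemia virus had 22685 (56.4 in pure mouse RNA), that for the 5' repeat of Moloney murine sarcoma virus 20205 (53.6), NeoR 8176 (65.8), eGFP 3370 (58.5) and the extended packaging signal 176.5 (58.4). In pure mouse RNA the probe specific for SV40 large T antigen had 301.1 (51.9 in pure human RNA) and the probe common to large T and small t 330.7 (70.9). A probe for the avian retrovirus receptor TV-A had 73.5 in pure human RNA, just above that array's threshold of 71.3, and 74.0 in pure mouse RNA, under its threshold of 75.7.

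Unspecific binding of human RNA to such probes and a murine retroviral vector with eGFP and NeoR in the MDA-MB-231 cells cannot be told apart. Above background in pure human RNA were 18.9% of these probes and 14.4% of all other mouse probes, which decides nothing about the bright ones. The rank correlation of 0.933 of eGFP and NeoR with the labelled human share would hold for any probe bright in human RNA, whatever it binds. Both SV40 T antigen probes followed the labelled mouse share (lower rank correlation 0.885), which leaves open in the same way whether the astrocytes might express large T antigen; the probe specific for small t stayed at background in both pure RNAs (62.8 in mouse, 51.8 in human). The labels name neither, and probe sequences were not used here.

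Duplicates of the 70% shares differed in brightness on both array types. On the human arrays, probes that read mouse RNA were also brighter in t1 than in t2, with a median ratio of 1.38 (43 probes, 95% interval 1.36 to 1.47), where a larger human share in t1 would have made them dimmer. Human-specific probes had a ratio of 1.31 (6211 probes), so the human arrays argue against different RNA proportions as the cause there and go with array brightness. On the mouse arrays of these mixtures the measured mouse share was 17.7% in t1 and 26.6% in t2, as a larger human share in t1 would give. Equally bright probes stood at 0.635 and 0.835 of their pure level there. Scaled by those probes the shares were 32.5% and 35.4%, so a small difference in proportions is left open. On the mouse arrays, probes that read human RNA had a ratio t4 over t3 of 1.16 (25 probes, 1.01 to 1.23), which is consistent with array brightness too. Beside the ratio of 1.252 for the mouse-specific probes (7330 probes), a small difference in proportions on top of it cannot be told apart, since the interval lies under that ratio but above 1, and no biological explanation was tested.

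Measured shares of the 2 species summed to less than 100% in the mixtures labelled s or t. Dimmer arrays may account for this: probes about equally bright on both pure arrays were dimmer on all 12 of those arrays, the highest ratio being 0.947. Saturation of bright probes is left open: it would push the sum above 100%, but the highest of the 6 sums, 93.1%, comes from dimmer arrays. Scaled by the equally bright probes, the sums of all 8 mixtures ran from 102.7% to 114.3%. On the deposited signal without that scaling, the brightest human-specific probes read 28.6% at a label of 30% against 20.9% for the dimmest. That signal is not background-corrected, and the lower background of these arrays also lowers the share read from dim probes. No biological explanation was tested.

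Random assignment of the shares was compared with both trends, which is a limited check. The mixtures are known dilutions on unscaled signal, so a high count for the real assignment follows from the design. Among 100 assignments of the shares to the human arrays only 1, the real one, called as many probes, 14102 against 13411 for the highest other. The same held for the mouse arrays, where 1 of 100 assignments, the real one, called 17460 probes and the highest other 14309.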

How the results depend on the processing

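The array series, the scaling by probes equally bright on both pure arrays, the 7 SD threshold and 75th percentile scaling for the gene lists were chosen after seeing the data. No paired analysis was possible because the s and t identifiers pair the 2 array types of 1 mixture and never 2 shares that are compared. A detection p-value as threshold could not be run, as no file used here gives one. Where a share was left with 1 array, that array was assumed to vary like the other groups. Signal over background limits the rest: at 10% of the own RNA 5850 of 6220 human-specific and 6954 of 7496 mouse-specific probes stayed above background. These probes were chosen as at least 4-fold brighter in their own RNA. Unless stated, the cause was not tested.

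Between the arrays, quantile normalization forces like distributions by construction. Under it the human trend had 2866 rising and 1589 falling probes and the mouse trend 2063 and 1415. At 70% against 30% it called 3095 (human, median 0.12) and 2587 (mouse, 0.11) probes, at 50% against 30% 2048 (0.076) and 2167 (0.080), and at 70% against 50% 781 (0.049) and 86 (0.034). Its measured shares at 10%, 30%, 50%, 70% and 90% were 71.2%, 89.1%, 96.2%, 98.9% and 99% on the human and 69.3%, 94.4%, 102.0%, 104.3% and 98.7% on the mouse arrays. It called 0 gene lists, the medians of the neuron (-0.19), fibroblast (-0.028) and endothelial (-0.17) lists turned, and slopes turned for ACTB (-1.28), CSPG4 (-1.36), GFAP (-1.41), H2AZ1 (-0.62), MBP (-1.0), PTMA (-0.062), RPL13AP3 (-1.30), RPS27 (-0.14), SLC25A5 (-0.15), SUMO2 (-1.11) and TPT1 (-1.02). Under 75th percentile scaling 4274 human probes fell, and 9835 mouse probes rose and 10601 fell. It shifts all slopes of an array type by the same amount, so flat probes can count as falling. The medians were 0.79 (human) and 0.60 (mouse) at 70% against 30% and 0.62 and 0.40 at 50% against 30%, 630 human probes were called at 70% against 50%, and 1 gene list was called. The medians of the neuron (-0.29), fibroblast (-0.31), endothelial (-0.0078) and microglia (-0.060) lists turned, and slopes turned for GFAP (-0.52), H2AZ1 (-0.29), PTPRC (-0.060), RPL13AP3 (-0.50), RPS27 (-0.34), SUMO2 (-0.55) and TPT1 (-0.55). Scaled by equally bright probes, 7836 human (median 0.38) and 3287 mouse probes were called at 70% against 50% and 11781 mouse probes at 50% against 30%, with a human median there of 0.53. The shares were then 34.0%, 72.9% and 91.4% (human at 30%, 70% and 90%) and 33.9%, 57.6% and 71.7% (mouse at 30%, 50% and 70%).

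The human 70% against 50% count of 0 became 353 without background correction, 355 with the processed and with the series matrix values, 12 with a filter of 3 arrays, 246 at 5 SD and 213 with robust empirical Bayes, which called 24 on the mouse arrays. Mouse probes called at 50% against 30% numbered 10306 without background correction and with the processed or series matrix values, 0 with the mode subtracted, 2922 without a filter and 10880 with robust empirical Bayes. Mouse probes falling in the trend numbered 256 without background correction and with the processed or series matrix values, 637 with the mode subtracted, 243 on mixed arrays only (fewer samples), 714 with the series as a block and 147 on the arrays labelled s or t, where 117 human probes fell. An estimated correlation left 0 gene lists, and fry, which does not compare a list with other genes, called 17. Probes above background in the other species numbered 7348 (human) at 2 SD, 2266 and 4419 (mouse) at 5 SD and 1847 and 3181 at 7 SD.

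Leaving out 1 array at a time gave 0 to 5601 calls for human 70% against 50% (median 0.041 to 0.39), 0 to 9241 for mouse 50% against 30% (0.44 to 0.83) and 0 to 12148 for mouse 70% against 30% (0.71 to 1.10). The human 70% against 30% median ran from 0.83 to 1.19, and the shares at 70% from 49.0% to 65.1% (human) and 46.6% to 60.0% (mouse). Of the remaining values, 178 for trends and contrasts, 94 for shares and 19 for gene lists stayed near the main value when no array was left out. Near means a count of similar size, a median or share within the SD between duplicates, or a list median within a fixed limit. Beyond that limit moved 32 list medians, 5 of them with a change of sign in a list that was not called. With 1 array left out 144 values for trends and contrasts and 8 for shares stayed near in the same sense. Single named genes stayed on their side of the threshold in 1510 cases, lost it in 131 and passed it in 6; with 1 array left out these were 1031, 7 and 2. Among those that stayed, 10 slopes under the threshold in both changed sign, all of GFAP, H2AZ1, RPL30, SUMO2 or TPT1.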

Other observations

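The values of this part were chosen after the main results were seen, and no significance test was run on them.

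Bright mitochondrial probes of the mouse arrays read high shares in most mixtures, and saturation is not excluded for them: ND1 had 39984 in pure mouse RNA, the highest signal of that array, and ATP6 had 19832 at 10% already. At 10% mouse RNA the share measured from the 12 mitochondrial probes above background in pure mouse RNA had a median of 24.6% (11.8% to 60.1%), and at 50% it had a median of 74.9% (1.43% to 94.9%). The dimmer ND5 (4855 in pure mouse RNA) read 12.6%, 30.3%, 58.0% and 66.7% at labels of 10%, 30%, 50% and 70%, and ND4L (16079) 13.6%, 11.3%, 24.6% and 31.7%, so high shares are not a trait of all of them. The low end is ND3, a subunit of complex I. Its probe had 2559 in pure mouse RNA, 1566 at 90% and 348.9 at 10% on arrays numbered 1, but 49.5 to 115.8 on the arrays labelled s or t, so its signal differed between the array series. The probe at position 301 of 18S ribosomal RNA had 15854 in pure human RNA on the mouse arrays, and 3 of 4 ribosomal RNA probes were above background in each pure RNA. Of 352 immune receptor gene segments 26 were above background in pure mouse and 37 in pure human RNA.

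Brighter human-specific probes read higher shares at labels up to 70%. On the human arrays the 622 brightest gave 13.0%, 28.6%, 53.9% and 63.1% at labels of 10%, 30%, 50% and 70%, and the 622 dimmest 9.54%, 20.9%, 44.2% and 52.6%, while both gave 84.2% at 90%. Among the 1974 probe keys that occur 2 times in the raw human table, both entries were above background in pure human RNA for 575, only the first for 14 and only the second for 720. Where both were above background, the log2 ratios of pure human to pure mouse RNA had a Spearman rho of 0.313 across keys, which are not independent replicates. The second entries were not used here. Among the named genes only the probe of TIMP2 has such a key, so its identity is uncertain.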
